A study of Arabidopsis thaliana with 4 samples.

How the data were processed

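RNA was measured in whole seedlings of Arabidopsis thaliana, 12 days old per the labels, from Col-0 (WT) and a sORF1511 overexpressor. Each of the 4 libraries held 200 ng of RNA from a pool of 5 seedlings and was made with a stranded, poly(A)-enriched Illumina protocol, per the labels' protocols. The labels call the 2 libraries of a genotype biological replicates. The design text names a single overexpressor line, 7, while the titles of these samples carry a longer code that the labels do not explain, so the line number is given as the design text has it. Effects of the line and of the transgene were not separated.

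The authors deposited 1 gene-level table per library with estimated counts, TPM, length and effective length for 33602 genes, per the file headers. The deposited estimated counts are expected read counts whose totals differ between libraries, and between 96.9% and 97.3% of them were whole within 0.001. The deposited TPM values are relative to effective length and scaled to a fixed sum over all genes of a library, chloroplast ribosomal RNA included. The quantifier, genome build and annotation are not given in the sources used here; the submitters' processing notes name DESeq2 without a version. Since no build was named, no coordinates are printed, and the gene reference of assembly TAIR10.1 served for names only, with 32835 of 33602 identifiers matched. Counting of near-identical copies is not described in the sources used here, so genes with close paralogs, such as the Rubisco small subunits, carry that uncertainty.

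Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by genotype (minimum count 10, minimum total 15), TMM scaling, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 19474 genes kept. The SE of a log2 fold change was the size of edgeR's unshrunk coefficient, on the log2 scale, divided by the square root of the F statistic. The fold changes printed are edgeR's shrunken ones, so the SE matches them only approximately where a genotype had few reads. CPM values use TMM-scaled library sizes. Totals ranged from 13974460 to 25740234 reads, so that 3 reads, the smallest level taken as measured, correspond to between 0.108 and 0.268 CPM. Where WT held 1 to 3 reads, a ratio with its exact 95% counting interval is given in place of the fitted fold change. PCR copies cannot be told apart, so such intervals cover counting error only.

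A total of 28 gene lists with 477 genes were fixed from textbook knowledge before the data were examined, with chloroplast- and mitochondrion-encoded genes as further sets, 30 in all. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), then with an estimated correlation and with fry. The rule for named genes was fixed at the same time and takes 8 flowering genes in every case (FT, SOC1, CO, FLC, SVP, TSF, LFY and AP1). It adds the 12 largest and 12 smallest fold changes past the threshold with a mean of at least 1 CPM and no overlap between genotypes, up to 4 members of each list, and the 5 smallest adjusted p in each direction. EM6 and other members of short lists fall under the list part of that rule.

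The tests were checked on simulated data, with 200 genes changed by known folds among counts drawn from the real means. Dispersions were drawn around edgeR's trend, as its model assumes; an earlier version of the simulation with gene-wise dispersion estimates gave more false calls and was replaced, so the false calls given here hold under that model. In that simulation of overexpressor against WT, on 19252 genes, edgeR called 0% of genes changed 2-fold, 16.4% of those changed 4-fold and 62.1% of those changed 16-fold, with 2 false calls. DESeq2 1.42.0 called 28.4%, 74.6% and 95.5% on 19474 genes, with 100 false calls. Limma-voom called 0%, 19.4% and 54.5%, with 2 false calls, and limma-trend on log2 TPM 1.49%, 22.4% and 63.6%, with 4. The replicate number as a block left edgeR with 0% called at each fold. A simulated list shifted by 1 on the log2 scale had an adjusted p of 2.2e-14 with camera, and 0 of 20 unshifted lists passed. The simulated genes were drawn independently, so this check cannot show false calls from lists whose genes vary together. In the data estimated correlations ran from -0.040 for cell division to 0.945 for chloroplast-encoded genes, with 0.72 for the abscisate list.

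The alternatives were DESeq2 with its own filtering, limma-voom, RLE factors, scaling by library size only, no low-count filter, a filter of at least 1 CPM in 2 libraries, effective length as an offset, limma-trend on log2(TPM + 1), the replicate number as a block, organelle genes left out before scaling, and each library left out in turn. In the last case the lone library of a genotype is taken to vary like the other genotype. Replicates of a genotype differed by more than sampling noise, with chi-square per degree of freedom of 380 in WT and 8.80 in the overexpressor, so none was counted as a duplicate. Chloroplast ribosomal RNA genes were included, so the WT value also holds their excess in WT replicate 1. It does not measure the spread of most genes. Plots were drawn with matplotlib 3.10.9.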

Results

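The series asks which small open reading frames encode phloem peptides with a putative part in the timing of flowering in Arabidopsis thaliana. The RNA-seq experiment compared seedlings of the reference accession Col-0 (WT) with a transgenic overexpressor of the small open reading frame sORF1511, named line 7 in the design text. Seedlings were 12 days old, and each genotype was represented by 2 libraries, which the labels call biological replicates, each made from a pool of 5 seedlings. Total estimated reads were 13974460 and 24508631 in WT replicates 1 and 2, and 18547136 and 25740234 in overexpressor replicates 1 and 2. The transcript of sORF1511 itself was not analysed here, because the tables and the gene reference used here do not carry that name. Expression values are CPM, read counts scaled by TMM to a common library size, and differences are log2 fold changes of overexpressor over WT ± SE from edgeR.

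The libraries differed in RNA composition. Chloroplast ribosomal RNA genes took 28.1% of the reads of WT replicate 1 (95% exact binomial interval 28.0 to 28.1), against 1.29% in WT replicate 2, 1.08% in overexpressor replicate 1 and 0.956% in overexpressor replicate 2. Reads of nuclear genes numbered 9541338 in WT replicate 1 and 24149362 in WT replicate 2, and 18333023 and 25478071 in overexpressor replicates 1 and 2. Pearson's correlation of log2 CPM across genes, which are not independent replicates, was 0.954 between the WT pools and 0.983 between the overexpressor pools. Intervals on read counts cover counting error only.

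**Figure D1:**
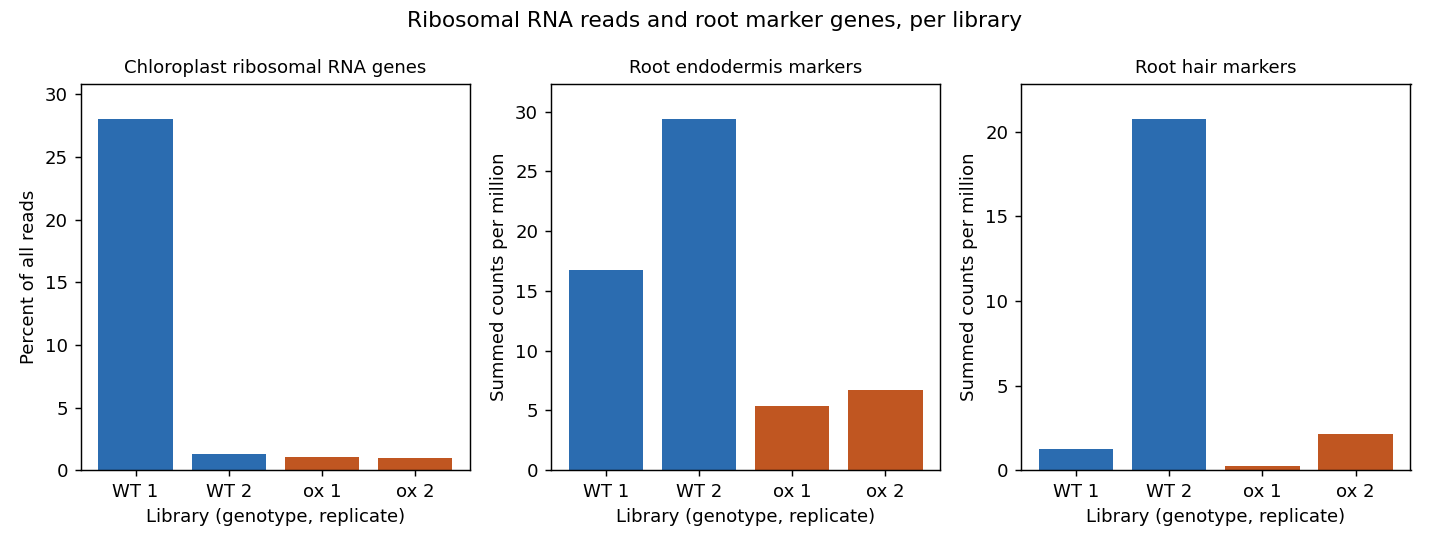
Bars give, for each of the 4 libraries, the percent of reads from chloroplast ribosomal RNA genes and the summed CPM of the root endodermis and root hair marker genes; each bar is 1 library and there are no error bars. WT replicate 1 stands apart at 28.1% ribosomal reads, and the endodermis markers sum to 16.7 and 29.4 CPM in WT against 5.41 and 6.67 CPM in the overexpressor.

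Genes of the response to abscisate and water deficit, of leaf senescence and of jasmonate were higher in the overexpressor seedlings, with 3, 2 and 1 members past the threshold over all genes tested and 19 of 24, 12 of 15 and 12 of 20 adjusted over the list alone. As sets these lists passed camera with its preset correlation. With an estimated correlation camera's adjusted p was 0.617, a single value that Benjamini-Hochberg adjustment gave many lists alike. In that setting, which relies on the few residual degrees of freedom, a pass was hardly possible for any list. RAB18 (AT5G66400), a dehydrin induced by abscisate, stood at 19.3 ± 9.33 CPM (SD, n = 2) in WT and 575 ± 137 CPM (SD, n = 2) in the overexpressor. Over all genes tested, 27 rose and 2 fell in the overexpressor at an adjusted p below 0.05, out of 19474. All 29 differed by at least 2-fold with no overlap between the libraries of the genotypes, which chance gives for 33.3% of genes. Selecting genes by their difference in these same libraries made that nearly certain, so it is no separate support. The flowering integrator SOC1 was higher and the flowering repressor FLC lower, each past the threshold only when adjusted over the list alone. That adjustment treats each list by itself, with no correction across lists. Since whole seedlings were pooled, a change in these flowering genes was not separated from a difference in tissue share. Among all genes tested, 21.7% had an unadjusted p below 0.05 in edgeR's quasi-likelihood test, a background against which list counts should be read.

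Among the 27 genes that rose, the highest ratios belonged to genes nearly silent in WT. AT2G38240, an oxygenase of the 2-oxoglutarate family, had 1 WT read against 594 reads in the overexpressor, a ratio of 494 with a 95% counting interval of 88.4 to 19564. NATA1 (AT2G39030), an N-acetyltransferase, had 3 against 1079 reads, a ratio of 299 with an interval of 102 to 1454. SOM (AT1G03790), a zinc finger protein that represses seed germination, had 2 against 635 reads, a ratio of 264 with an interval of 72.9 to 2187. The glycosyltransferase gene AT2G36780 rose by 6.97 ± 0.61 on the log2 scale, although it lies among near-identical copies that can share reads. The phosphatase AHG1 (AT5G51760) rose by 4.91 ± 0.40, and the transcription factor RAP2.9 (AT4G06746) by 4.47 ± 0.35. The glutathione transferase GSTU4 (AT2G29460) rose by 4.12 ± 0.20, from 0.683 ± 0.0454 to 11.8 ± 0.27 CPM (SD, n = 2 each). It shared the smallest adjusted p of 0.0236 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment with AT2G38240 and NATA1. The kinase MAPKKK18 (AT1G05100) rose by 3.65 ± 0.30, and the gene AT5G54165 went from 0.585 ± 0.195 to 7.61 ± 0.195 CPM (SD, n = 2 each).

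Smaller rises past the threshold included 2 genes of sucrose breakdown, the sucrose synthase SUS1 (AT5G20830), from 25.1 ± 5.16 to 101 ± 1.69 CPM (SD, n = 2 each), and the neutral invertase A/N-InvC (AT3G06500), at 2.01 ± 0.15 on the log2 scale. The stress-induced NAC transcription factors NAC032 (AT1G77450) and ATAF1 (AT1G01720) rose by 1.90 ± 0.16 and 1.70 ± 0.15. The photoreceptor-like PLPB (AT2G02710) rose by 1.64 ± 0.10, and AFP3 (AT3G29575), a binding partner of the abscisate factor ABI5, by 1.45 ± 0.13. UGT74F2 (AT2G43820), a salicylate glucosyltransferase, went from 7.42 ± 1.78 to 69.9 ± 1.55 CPM (SD, n = 2 each). The genes that fell were AT3G16670, of the pollen Ole e 1 and extensin family, which fell by 1.40 on the log2 scale (SE 0.11), and the TRAF-like gene AT5G26280, which fell by 1.60 (SE 0.12). AT3G16660, of the same family as AT3G16670, stood at 41.7 ± 2.66 CPM in WT and 17.5 ± 1.59 CPM in the overexpressor (SD, n = 2 each), with an adjusted p of 0.0518 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lipid-transfer-like gene AT5G46900 had 98 WT reads and 1 overexpressor read, and AT4G12520 had 251 and 6, with adjusted p of 0.0521 and 0.0518 in that edgeR test after Benjamini-Hochberg adjustment.

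The abscisate, drought and cold list held 24 tested genes, all with higher values in the overexpressor and a median log2 fold change of 2.08. Of these, 3 rose over all genes tested, and 19 rose and 0 fell adjusted over the list alone. Past the threshold over all genes were RAB18 at 4.87 ± 0.41, the homeodomain factor HB12 at 2.35 ± 0.14 and the phosphatase ABI2, a negative regulator of abscisate signalling, at 1.77 ± 0.15. ABI1, its close relative, had a log2 fold change of 1.47 ± 0.14 and rose when adjusted over the list alone. As a set the list ranked higher than other genes (camera, Benjamini-Hochberg adjusted p = 2.1e-13), and adjusted p = 0.617 with an estimated correlation. The WT pools also differed in these genes, with 23 of 24 higher in WT replicate 2 than in WT replicate 1 and a median log2 ratio of 0.84. The 19 remained 19 in number without WT replicate 1, whose share of ribosomal reads stood apart.

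**Figure D2:**
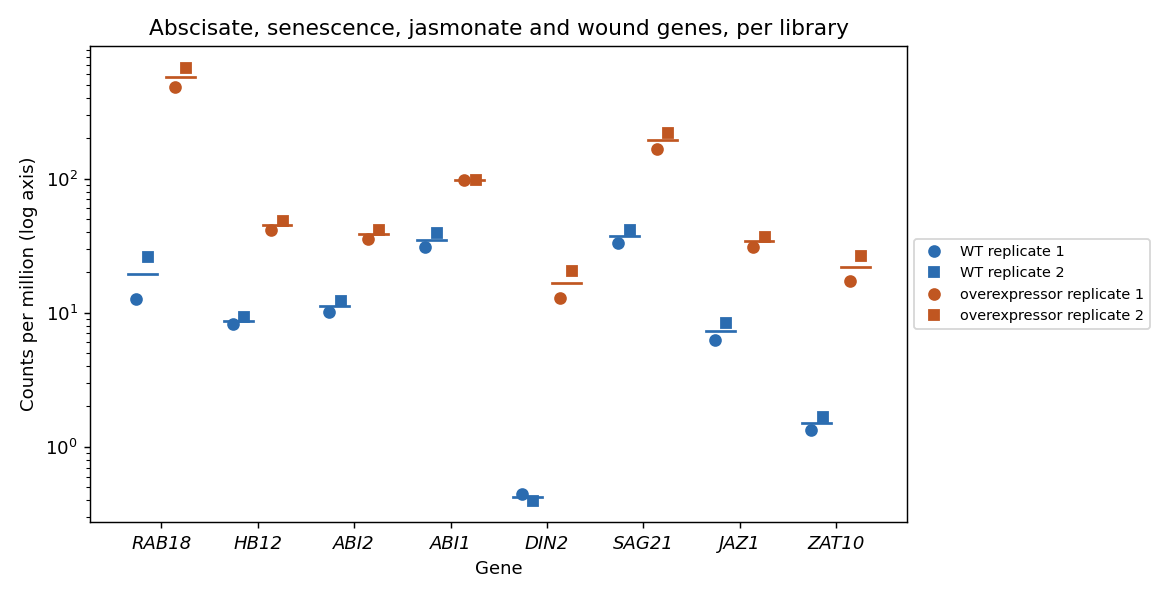
CPM on a log axis for 8 genes of the abscisate, senescence, jasmonate and wound lists in each library; circles are replicate 1, squares replicate 2, and horizontal bars the mean of the 2 libraries of a genotype. Both overexpressor libraries lie above both WT libraries for every gene shown, with RAB18 at 12.7 and 25.9 CPM in WT and 478 and 671 CPM in the overexpressor.

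Leaf senescence genes showed a median log2 fold change of 2.35 over 15 tested members. Of them 2 rose over all genes tested, and 12 rose and 0 fell adjusted over the list alone. DIN2, a beta-glucosidase induced in the dark and by sugar depletion, rose by 5.32 ± 0.35, and SAG21, a late embryogenesis abundant protein, by 2.35 ± 0.19. ORE1, a NAC factor that promotes leaf ageing, had 0.447 and 1.05 CPM in WT and 7.54 and 10.8 CPM in the overexpressor and rose adjusted over the list alone, as did SAG14 at 3.37 ± 0.35. The set test gave a Benjamini-Hochberg adjusted p of 1.3e-07 with camera, and adjusted p = 0.617 with an estimated correlation. The median became 1.91 without WT replicate 1 and 3.99 without WT replicate 2. It was 2.29 without overexpressor replicate 1 and 2.19 without overexpressor replicate 2. Between the WT pools these genes had a median log2 ratio of 0.99, higher in WT replicate 2.

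In the sugar starvation and trehalose list, 0 of 16 genes passed over all genes tested and 6 rose adjusted over the list alone, with a median of 0.70. TPS11, of the trehalose phosphate synthase family, stood at 1.36 ± 0.16, the beta-amylase BAM5 at 4.12 ± 0.72 and the plastid glucose phosphate translocator GPT2 at 1.73 ± 0.39. Members of the list need not respond to sugar in the same direction, so neither its median nor its count measured sugar starvation. For this list camera gave a Benjamini-Hochberg adjusted p of 0.00906, and adjusted p = 0.617 with an estimated correlation. Without overexpressor replicate 2 the count was 3, and without WT replicate 1 it was 6 higher and 1 lower, with a camera Benjamini-Hochberg adjusted p of 0.088.

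Jasmonate genes were higher in the overexpressor for all 20 tested members, with a median of 0.89. Of these, JAZ1, a repressor of jasmonate signalling, rose over all genes tested, from 6.26 and 8.35 CPM in WT to 31.1 and 36.9 CPM in the overexpressor, and 12 rose and 0 fell adjusted over the list alone. The lipoxygenase LOX3 rose by 1.34 ± 0.17 in the latter count, the storage proteins VSP2 and VSP1 by 1.89 ± 0.27 and 2.77 ± 0.42. Camera gave a Benjamini-Hochberg adjusted p of 1.3e-07, and adjusted p = 0.617 with an estimated correlation. The 12 became 9 without WT replicate 1 and 5 without overexpressor replicate 1.

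Early immune and wound genes had 1 rise over all genes tested, the zinc finger repressor ZAT10 at 3.83 ± 0.29, and 4 of 16 rose adjusted over the list alone, with ZAT12, NHL10 and WRKY33 beside it. Salicylate genes had 0 of 19 past the threshold over all genes tested, and 4 rose adjusted over the list alone. These were PBS3, an enzyme of salicylate synthesis, at 2.29 ± 0.26, CBP60G, an activator of it, at 1.59 ± 0.32, the pathogenesis-related gene PR5 at 1.04 ± 0.20 and WRKY18 at 0.98 ± 0.18. Of 17 heat shock genes, 0 passed over all genes tested and 3 rose adjusted over the list alone. Among them were the factors HSFA2 at 2.51 ± 0.35 and DREB2A at 3.98 ± 0.72, the latter better known for its induction by drought. With scaling by library size only, 8 heat shock, 7 immune and 6 salicylate genes rose adjusted over the list alone. Camera's Benjamini-Hochberg adjusted p was 0.00906 for the immune list, 0.0149 for salicylate and 9.6e-05 for heat shock, and for each of them adjusted p = 0.617 with an estimated correlation. The heat shock median was 1.04, or 0.57 without WT replicate 1 and 1.69 without WT replicate 2, and the same genes had a median log2 ratio of 1.22 between WT replicate 2 and WT replicate 1. Counts adjusted over the list alone were, without WT replicate 1, 3 immune, 5 salicylate and 4 heat shock genes, and camera's Benjamini-Hochberg adjusted p rose to 0.091 for the immune and 0.085 for the salicylate list. Without WT replicate 2 the heat shock count was 11, without either overexpressor library it was 0, and without overexpressor replicate 2 the salicylate count was 0.

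Flowering genes are the subject of the series. Of 14 tested floral promoters 0 passed over all genes tested and 1 rose adjusted over the list alone. This was SOC1 (AT2G45660), a MADS-box integrator of flowering signals, at 9.44 ± 0.561 CPM in WT and 16.2 ± 0.587 CPM in the overexpressor (SD, n = 2 each), a log2 fold change of 0.78 ± 0.13. Its adjusted p was 0.0936 over all genes and 0.0215 adjusted over the list alone, both from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. FT (AT1G65480), the mobile florigen made in the phloem, had 1.22 ± 0.0412 CPM in WT and 1.06 ± 0.113 CPM in the overexpressor (SD, n = 2 each), a log2 fold change of -0.20 ± 0.33, and no difference was detectable at this depth. CO (AT5G15840), which activates FT in long days, had 16 WT and 15 overexpressor reads and a log2 fold change of -0.56 ± 0.84, which turned to 0.31 without WT replicate 1. TSF, LFY and AP1 had too few reads for a test, with 3, 6 and 0 reads in WT and 7, 0 and 2 in the overexpressor. FKF1, a blue-light receptor of the photoperiod pathway, had 0.179 and 0.362 CPM in WT and 1.35 and 4.52 CPM in the overexpressor and did not pass adjusted over the list alone.

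Among 23 tested floral repressors, 0 passed over all genes tested, and 0 rose and 2 fell adjusted over the list alone. FLC (AT5G10140), the vernalization-sensitive repressor, had 13.7 ± 1.49 CPM in WT and 5.12 ± 1.36 CPM in the overexpressor (SD, n = 2 each) and fell by 1.43 on the log2 scale (SE 0.23). Its relative MAF5 fell by 0.98 (SE 0.18). The pools were whole seedlings, and root endodermis markers were lower in the overexpressor pools. Whether a different share of root tissue contributes to the lower FLC and MAF5 values was not tested. The adjusted p of FLC was 0.0914 over all genes and 0.0269 adjusted over the list alone, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Under the replicate block, and with limma-trend on log2(TPM + 1), 0 repressors fell adjusted over the list alone. SVP (AT2G22540), a repressor that acts with FLC, had a log2 fold change of 0.53 ± 0.13 and MAF4 one of -1.09 ± 0.29, neither past the threshold. Camera gave a Benjamini-Hochberg adjusted p of 0.0367 for the promoters, and adjusted p = 0.617 with an estimated correlation. For the repressors camera gave a Benjamini-Hochberg adjusted p of 0.977. Leaving out overexpressor replicate 2 left 0 past the threshold in both lists. Leaving out WT replicate 1, WT replicate 2 and overexpressor replicate 1 in turn gave 4, 4 and 1 repressors lower, 0, 5 and 0 higher, and 1, 2 and 1 promoters higher. The promoter set call ended without WT replicate 2 and without overexpressor replicate 2, with camera Benjamini-Hochberg adjusted p of 0.079 and 0.146, and with no low-count filter, at 0.080.

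**Figure D3:**
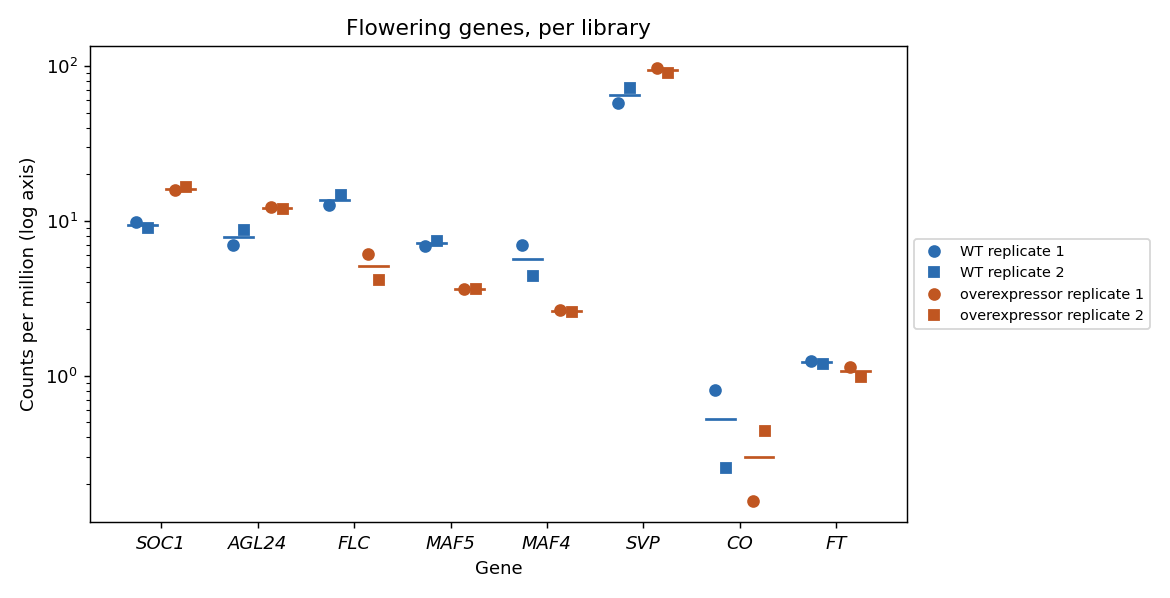
CPM on a log axis for 8 flowering genes in each library; circles are replicate 1, squares replicate 2, and horizontal bars the mean of the 2 libraries of a genotype. SOC1 lies at 9.83 and 9.04 CPM in WT and 15.8 and 16.6 CPM in the overexpressor, FLC at 12.6 and 14.7 against 6.09 and 4.16 CPM.

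The circadian clock list had 25 tested genes, of which 0 passed over all genes tested and 1 rose adjusted over the list alone, the evening gene ELF4 at 2.79 ± 0.49. The median of the list was 0.16, or 0.30 without WT replicate 2. Morning and evening genes are pooled in it, so neither the median nor a set test gives a direction for the clock. Camera gave a Benjamini-Hochberg adjusted p of 0.0315, and adjusted p = 0.617 with an estimated correlation. With scaling by library size only 3 clock genes rose adjusted over the list alone. No clock gene passed without WT replicate 1, WT replicate 2 or overexpressor replicate 2, when 0 rose, and 2 rose without overexpressor replicate 1. The set call ended without WT replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.103).

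Cell division genes were lower in the overexpressor for all 17 tested members, each with no overlap between genotypes, at a median log2 fold change of -0.55. Over all genes tested 0 passed, and 10 fell adjusted over the list alone. The mitotic cyclin CYCB1;2 fell by 0.79 (SE 0.14), the mitotic kinase CDKB2;1 by 0.72 (SE 0.12) and the cytokinesis syntaxin KN by 0.55 (SE 0.09). Camera gave a Benjamini-Hochberg adjusted p of 1.3e-07, and adjusted p = 0.617 with an estimated correlation. The 10 became 7 without WT replicate 1, 12 without WT replicate 2, and 0 without either overexpressor library or with scaling by library size only.

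Phosphate starvation genes had a median of -0.69 over 12 tested members, with 0 past the threshold over all genes tested and 3 that fell adjusted over the list alone. These were SPX1, a phosphate sensor, which fell by 0.66 (SE 0.10), and the root phosphate transporters PHT1;4 and PHT1;1, which fell by 1.17 (SE 0.27) and 2.17 (SE 0.56). Root endodermis markers were lower too, and phosphate genes, like the endodermis and root hair markers, were higher in WT replicate 2 than in WT replicate 1, by a median of 0.78 on the log2 scale. In the phloem and companion cell list of 21 genes, 0 passed over all genes tested and 1 fell adjusted over the list alone. This was the sieve-plate callose synthase CALS7, which fell by 1.16 (SE 0.20). The phloem median was -0.34, or -0.19 without WT replicate 2. Camera gave a Benjamini-Hochberg adjusted p of 0.00906 for both lists, and adjusted p = 0.617 with an estimated correlation. Without WT replicate 1 the counts were 10 lower phosphate genes and 5 lower phloem genes. The phosphate median became -1.06 without WT replicate 1 and -0.072 without WT replicate 2, when camera's Benjamini-Hochberg adjusted p was 0.417 for phosphate and 0.280 for phloem genes. Camera's adjusted p after Benjamini-Hochberg adjustment was 0.063 for phloem genes without overexpressor replicate 1 and 0.080 for phosphate genes without overexpressor replicate 2. Without WT replicate 2 the counts were 1 lower phosphate gene, and 4 lower and 1 higher phloem genes, and without either overexpressor library both were 0.

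The summed root endodermis markers were 23.1 ± 8.97 CPM in WT and 6.04 ± 0.893 CPM in the overexpressor (SD, n = 2 each). Of 4 endodermis genes tested, 0 passed over all genes tested and 3 fell adjusted over the list alone, with CASP1, which builds the Casparian strip, down from 4.38 and 7.60 CPM to 0.520 and 0.912 CPM. The root hair markers summed to 1.25 and 20.8 CPM in the WT pools and 0.26 and 2.15 CPM in the overexpressor pools, and PRP3, the only member with enough reads for a test, did not pass. Iron homeostasis genes had 0 of 17 past the threshold either way. They included the root uptake transporter IRT1 at 0.447 and 12.2 CPM in WT and 0 and 0.438 CPM in the overexpressor. Its regulator FIT stood at 1.43 and 2.97 against 0.416 and 0.328 CPM. Adjusted over the list alone, 4 iron genes were lower with library size only and 2 under the replicate block. DESeq2 gave 3 lower and 1 higher of 23 tested. Camera gave the iron list a Benjamini-Hochberg adjusted p of 0.292, and 9.3e-04 without WT replicate 1 and 0.034 with library size only, with adjusted p = 0.617 with an estimated correlation. Adjusted over the list alone, 7 iron genes were lower and 1 higher without WT replicate 1, 1 was higher without WT replicate 2, and 0 passed without either overexpressor library. Lower endodermis genes numbered 6 of 6 tested without WT replicate 1, 2 of 4 without WT replicate 2, and 2 and 3 of 6 without overexpressor replicates 1 and 2. Lower root hair genes numbered 6 of 6 without WT replicate 1 and 0 in the other fits with 1 library left out, and the only gene tested without WT replicate 2 stood at 0.10.

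Anthocyanin and flavonoid genes had 0 of 15 members past the threshold over all genes tested, and 9 rose adjusted over the list alone, at a median of 0.47. The entry enzyme CHS stood at 0.50 ± 0.12 and UF3GT, a late glycosyltransferase, at 0.77 ± 0.17. Nuclear photosynthesis genes had 0 of 25 past the threshold either way, with a median of 0.24, or 0.16 without WT replicate 1. Adjusted over the list alone, 6 rose with organelle-encoded genes left out, 5 with limma-voom and 12 with DESeq2. In this list RBCS1B, a Rubisco small subunit with near-identical copies, stood at 0.47 ± 0.12. Camera gave Benjamini-Hochberg adjusted p of 3.6e-04 and 4.3e-04 for these lists, and adjusted p = 0.617 with an estimated correlation. The 9 anthocyanin genes became 10 without WT replicate 1, 1 without WT replicate 2, and 0 without overexpressor replicate 2 or with scaling by library size only. Of 10 nitrate response genes, 0 passed over all genes tested and 3 rose adjusted over the list alone, the nitrate reductases NIA1 and NIA2 and the regulator LBD39, at 0.39 ± 0.08, 0.43 ± 0.11 and 0.58 ± 0.09. The count of risen nitrate genes was 2 without WT replicate 1 and 0 without either overexpressor library or with scaling by library size only. Transcripts encoded in the chloroplast had a median of -5.20 over 68 genes, with 0 past the threshold over all genes tested and 61 that fell adjusted over the list alone. Without WT replicate 1, which held the excess of ribosomal reads, that median was -1.23, with 34 genes lower and 2 higher, and without either overexpressor library or with limma-voom 0 were lower. Those encoded in the mitochondrion had a median of -3.88 over 29 genes, with 0 past the threshold either way, and a median of -0.58 without WT replicate 1. Adjusted over the list alone, 46 of 48 tested mitochondrial genes were lower without WT replicate 2, 1 of 28 without WT replicate 1, and 27 of 29 with scaling by library size only. Camera gave Benjamini-Hochberg adjusted p of 1.5e-09 and 9.6e-05 for the organelle sets, and adjusted p = 0.617 with an estimated correlation.

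**Figure D4:**
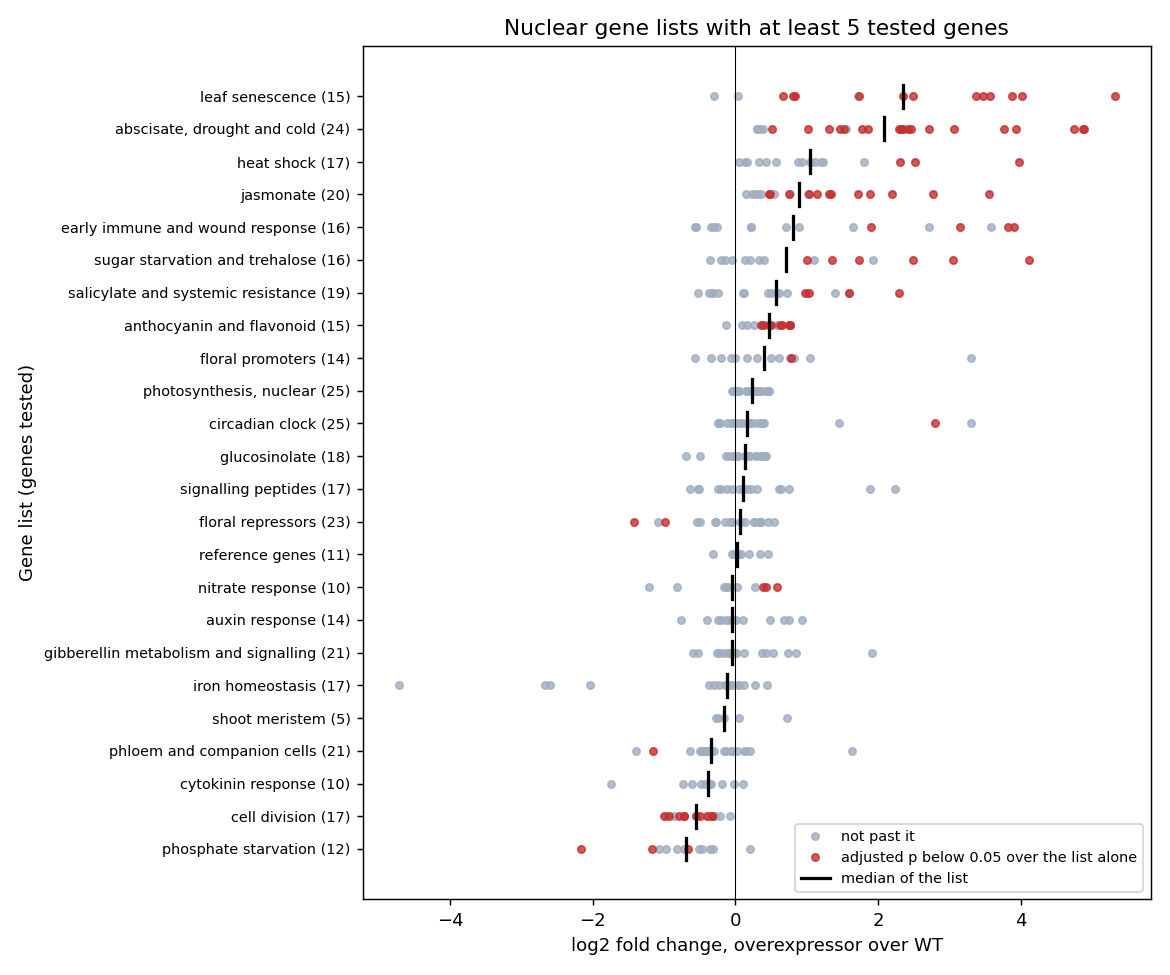
Each dot is the log2 fold change of 1 tested gene, overexpressor over WT, in the nuclear gene lists with at least 5 tested genes, the organelle-encoded sets left out; red dots passed an adjusted p below 0.05 over the list alone, grey dots did not, and black bars are list medians. Among the lists drawn, senescence and abscisate genes have the highest medians, 2.35 and 2.08, and phosphate starvation and cell division genes the lowest, -0.69 and -0.55.

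In the gibberellin, glucosinolate, auxin, cytokinin, signalling peptide, shoot meristem and reference gene lists, 0 genes passed over all genes tested or adjusted over the list alone. Adjusted over the list alone, 4 cytokinin genes were lower and 1 gibberellin gene and 2 reference genes higher without WT replicate 2, and 1 cytokinin gene was lower and 2 gibberellin genes higher without WT replicate 1. In the other settings at most 2 genes of any of these lists passed. Cytokinin genes had a median of -0.39 (camera, Benjamini-Hochberg adjusted p = 0.051), which ran from -0.17 without WT replicate 1 to -0.57 without WT replicate 2. That set passed camera after Benjamini-Hochberg adjustment without WT replicate 2 (adjusted p = 0.0076), overexpressor replicate 1 (0.0083) or overexpressor replicate 2 (0.041), and with library size only (0.00996), no low-count filter (0.014) or log2(TPM + 1) (0.0089); adjusted p = 0.617 with an estimated correlation. Reference genes, used to normalise quantitative PCR, had a median of 0.03. The medians were -0.05 for gibberellin, 0.14 for glucosinolate, -0.05 for auxin, 0.11 for signalling peptides and -0.16 for shoot meristem genes. The shoot meristem median ran from -0.040 without WT replicate 1 to -0.30 without overexpressor replicate 1. The glucosinolate set passed camera after Benjamini-Hochberg adjustment without overexpressor replicate 2 (higher, adjusted p = 0.0032), against 0.457 with all libraries and 0.912 with an estimated correlation. Median, mean and test differed in sign for the gibberellin, auxin, shoot meristem, nitrate and floral repressor lists. The gibberellin, auxin and nitrate medians turned positive with scaling by library size only, and these and the glucosinolate, signalling peptide and reference gene medians changed sign in at least 1 fit with a single library left out. Of the floral organ genes, 0 of 4 tested passed. The late embryogenesis gene EM6, the only testable seed storage member, had 1.05 ± 1.48 CPM in WT (SD, n = 2) and 18.3 and 21.7 CPM in the overexpressor pools and rose adjusted over the list alone, where the list was that gene.

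Calls came from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. At an unadjusted p below 0.05 the test gave 4233 genes, 21.7% of those tested, 2323 higher and 1910 lower. Counts adjusted over a list alone were not corrected across lists. With 2 libraries against 2 there are 3 splits of the samples, so no permutation test could reach 0.05. Across the lists, 16 of 26 tested passed with camera's preset correlation, 11 higher and 5 lower, the 5 including both organelle-encoded sets. With an estimated correlation or with fry 0 passed. With an estimated correlation camera relies on the few residual degrees of freedom, so a pass was hardly possible. Cell division had an estimated correlation of -0.040, below the preset 0.01, yet its unadjusted camera p went from 1.5e-08 to 0.026. The adjusted p of 0.617 was shared by lists with unadjusted camera p from 0.026 to 0.451. All 29 called genes kept their sign in every alternative, which the lack of overlap between their libraries made nearly certain. The count depended on the tool and on single libraries. DESeq2 called 912 higher and 307 lower and limma-voom 0, while scaling by library size only, which shifted the median of all genes to 0.10, gave 570 higher and 239 lower. With limma-trend on log2(TPM + 1), 0 members passed adjusted over the list alone in the floral promoter, floral repressor, cell division, anthocyanin, nitrate, phosphate and phloem lists. The share called higher was 93.1% with TMM and 70.5% by library size only. Without WT replicate 1 the counts were 240 higher and 140 lower, without WT replicate 2 they were 1189 and 1014, without overexpressor replicate 1 they were 1 and 0, and without overexpressor replicate 2 both were 0.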

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

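All alternatives were planned, and none was chosen after seeing the data. The counts of genes higher, lower and changed at least 2-fold were 27, 2 and 29, and stayed within 1.5 times of these with RLE factors and the effective length offset. They became 912, 307 and 634 with DESeq2, 570, 239 and 809 with library size only, and 305, 57 and 293 without the low-count filter. They became 65, 10 and 72 with the stricter filter, 250, 24 and 274 with limma-trend on TPM, and 163, 21 and 159 without organelle-encoded genes. With limma-voom they were 0, 0 and 0, with 4081 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.0598. Leaving out 1 library gave 0 to 1189 genes higher, 0 to 1014 lower and 0 to 1038 changed 2-fold. Of these, the fits with fewest calls kept 1 overexpressor library, where the spread comes from the WT pair alone. Without overexpressor replicate 2, edgeR gave 1489 genes at an unadjusted p below 0.05. In data simulated from edgeR's own model DESeq2 made 100 false calls and edgeR 2. That model favours edgeR by construction and has no odd WT replicate 1, so it cannot account for the differences in the data. The cause of the differences was not tested. All 29 called genes kept their sign in every alternative, as genes without overlap between genotypes nearly must. They were called again in all but limma-voom (0 of 29), the offset (21), and the fits without overexpressor replicate 1 or 2 (0 each).

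The paired fit, with the replicate number as a block, gave 329 higher, 43 lower and 324 changed 2-fold, and 17 lists. In the simulation this fit called 0% of genes changed 16-fold, yet here it called more genes than the main fit. The simulation thus does not describe how the paired fit behaves on these data. Under the block 0 floral repressors and 0 phloem genes passed adjusted over the list alone, against 2 and 1, 6 cell division genes against 10, 4 anthocyanin genes against 9, and 41 lower chloroplast-encoded genes against 61. For genes encoded in the mitochondrion 4 were lower, against 0. The cytokinin list was past the threshold under the block (camera, Benjamini-Hochberg adjusted p = 0.017). The numbers are not known to pair the samples: there are 2 pairs, and their deviations correlate at 0.06 over genes. The 16 lists past the threshold became 0 with an estimated correlation and 0 with fry, and ranged from 14 to 18 with 1 library left out.

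Of the 136 named and top list genes, only genes with no call changed sign. CO was 0.31 without WT replicate 1 (range with 1 library left out -1.60 to 0.31), and SEP3 -0.25 without overexpressor replicate 1 (-0.25 to 0.75). Leaving out WT replicate 2 gave SEP4 -0.014 (-0.014 to 0.20), PI -0.53 (-0.53 to 1.23) and PRP3 0.10 (-6.43 to 0.10). The cause was not tested. Depth limits genes with few reads: TSF, LFY and AP1 had at most 7 reads per genotype.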

Other observations

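The family tests and the tests of explanations in this part were chosen after the results they concern had been seen, while leaving out WT replicate 1 was planned. Gene families were taken by symbol stem, 124 of them with at least 10 tested genes. A shared stem need not mean a true gene family. The RAP stem holds RAP74 and RAP beside the RAP2 factors, and the JAZ stem repeats members of the jasmonate list. UDP-glycosyltransferases (UGT) ranked higher in the overexpressor over 50 tested genes, 37 of them with a positive fold change (camera, Benjamini-Hochberg adjusted p = 2.2e-06). The call was lost with an estimated correlation, where camera gave an unadjusted p of 0.270. Its Benjamini-Hochberg adjusted p of 0.887 was shared by many other stems. That setting relies on the few residual degrees of freedom, so a pass was hardly possible and the loss decides nothing. Among genes with a UGT symbol 18 rose and 0 fell adjusted over the family alone, and 1, UGT74F2, rose over all genes tested. The glycosyltransferase gene AT2G36780, which also rose over all genes tested, has no such symbol here and was not counted. UGT76E12 stood at 0 and 0.47 CPM in WT and 22.1 and 28.4 CPM in the overexpressor, and UGT75B1, which can glucosylate abscisate, at 12.0 and 17.9 against 58.4 and 59.6 CPM. Camera gave a Benjamini-Hochberg adjusted p of 0.0040 without WT replicate 1. The RAP, MES, JAZ and GSTU stems also passed camera (Benjamini-Hochberg adjusted p = 0.010, 0.019, 0.023 and 0.0285), and each had adjusted p = 0.887 with an estimated correlation. Without WT replicate 1 their camera values after Benjamini-Hochberg adjustment were 0.014, 0.198, 0.014 and 0.617.

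The first pattern weighed was the rise of the abscisate, drought and cold genes. The odd WT replicate 1 library is argued against as its source, since the median log2 fold change without it was 1.75. Water status or handling of the pools at harvest may contribute and cannot be told apart from genotype, because each pool holds 1 genotype. The WT pools differed in these genes by a median log2 ratio of 0.84, which decides nothing with 1 pool on each side and the odd WT replicate 1 among them. An effect of the transgene remains open and was not tested further.

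Root marker genes were the second pattern. Less root tissue in the overexpressor pools cannot be tested with the endodermis sums, which only restate the pattern. There the highest overexpressor library was at 0.399 of the lowest WT library (95% counting interval 0.324 to 0.492). The root hair sums leave less root tissue open as well, at a ratio of 1.72 (0.948 to 3.33). Whether the share of root tissue changed alike for all root cell types stays open: between the WT pools the ratio of replicate 2 to replicate 1 for hair markers was 9.43 times that for endodermis markers, but with 1 pool on each side counting intervals leave out the spread between pools. A transgene effect on root genes stays open and untested.

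The third pattern was the excess of organelle transcripts in WT replicate 1. Less complete poly(A) selection in that library is a candidate explanation, since nuclear snRNA and snoRNA genes, which lack poly(A) tails, were higher there by a median log2 ratio of 5.34, in 11 of 11 genes. More chloroplasts or green tissue in that pool is argued against by the mitochondrion-encoded genes, higher by a median of 4.63 in 50 of 50 genes. Nuclear photosynthesis genes had a median of -0.15 in the same ratio.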
